A study of Gallus gallus with 9 samples.

How the data were processed

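RNA was measured in explants of chick splanchnic mesoderm, the tissue that holds the progenitors of the anterior heart field, a source of heart muscle and of muscle and connective tissue of the pharyngeal arches. Explants were taken at 0 h or cultured for 3, 12 or 24 h on collagen in serum-containing medium, without added factor or with human recombinant BMP4 at 200 ng/ml. Biotin-labelled total RNA was hybridised to 9 Affymetrix chicken arrays, 1 per sample. The 12 h samples were duplicated (A and B) in each arm, and every other group of the 7 holds 1 array.

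The deposited values are probe set signal intensity on a linear scale, made with MAS5 per the submitters' processing notes, which give no scaling target and no version. The 2% trimmed means of the 9 arrays lie between 503.66 and 504.72, so the values were used as deposited, without further scaling. The table holds 38535 probe sets with values from 1 to 43611.53. The 96 Affymetrix control probe sets were left out of the tests. The number of arrays limits the precision.

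Signals were put on a log2 scale after adding 27.79, the 25th percentile of the table. A probe set was tested when its signal exceeded the 40th percentile of its own array on at least 2 of the 9 arrays, which left 28329 probe sets and dropped 10110. Differences were tested with limma 3.58.1 in R 4.3.3, with moderated variances that follow a trend over the mean signal. The trend was used because the spread between arrays fell with signal, from a median residual SD of 0.434 in the dimmest 25% of the probe sets to 0.174 in the brightest 25%. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the 28329 probe sets. A difference was called at an adjusted p under 0.05, and errors after ± are standard errors of the log2 difference from the fit.

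The BMP4 effect across times and the effect of culture time over both agents came from a fit of the 8 cultured arrays with time and agent as terms, which leaves 4 residual degrees of freedom. The BMP4 effects at 12, 3 and 24 h, the change of the effect from 3 h to 24 h, and the untreated time course came from a fit of all 9 arrays with 7 group means. That fit has 2 residual degrees of freedom, all from the 12 h arrays, so lone arrays are assumed to vary like the 12 h samples. The labels leave open whether A and B are separate explant pools or the same RNA, so the p-values measure only the spread between these samples.

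Probe sets were named from the array annotation matched to the chicken RefSeq genes (assembly GRCg7b). Of all probe sets other than controls, 27168 carry 1 gene symbol, 177 carry several and 11094 carry none. Where the mean signal of a compared group lies under the added 27.79, the size of the log2 difference depends on the amount added, and the place of such a gene among the others is not read as a ranking. A gene is represented by its probe set with the highest mean, and 11675 named genes passed the filter. Genes named in the text followed a rule fixed before the data were examined. For the BMP4 effect across times these are the 15 highest and the 15 lowest called genes with the same sign at 3, 12 and 24 h. For other comparisons they are the 8 highest and 8 lowest called genes, or 5 and 5 for the change between times. Where under 5 genes were called, the genes with the greatest size of change among those with an unadjusted p under 0.01 were taken. Up to 4 called members of each gene list and a fixed set of regulators and contractile genes were added whatever they showed. Some leaders are given as summaries. Further called list members and the remaining genes called for the change between times are named beyond the rule because they were called. Other names outside the rule are marked in the text as chosen after their values were seen.

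The 24 gene lists, also fixed before the data were examined, cover BMP targets and feedback, FGF and ERK feedback, anterior heart field progenitors, cardiac transcription factors, and cardiomyocyte sarcomere and calcium genes. Others hold markers of craniofacial skeletal muscle, smooth muscle, endothelium, blood, neural crest, pharyngeal endoderm and epithelium, neural tissue, and limb, arch and outflow mesenchyme. The rest cover extracellular matrix, the cell cycle, cell cycle arrest and apoptosis, Notch, Wnt, hedgehog, retinoic acid, immediate early and heat shock genes, glycolysis and hypoxia, sterol synthesis, and interferon and inflammation. A member without a probe set of its symbol was matched by synonym where 1 gene carried it. KRT24 thus stands for KRT19, ALAS1 for ALAS2 and HES4 for HES1, among others. Lists were tested with limma's camera with a preset correlation of 0.01 between genes, with camera with an estimated correlation, and with fry, each adjusted over the 24 lists. With an estimated correlation camera uses only the residual degrees of freedom of the fit, 4 or 2, so few lists could pass it. A call lost there leaves open whether correlation between genes accounts for the shift. Counts of list members are given over all probe sets tested and adjusted over the list alone. Another 3 lists, of surface ectoderm and general epithelium, of placode and anterior neural ectoderm, and of the amino acid response, were written after the first results had been seen.

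The tests were tested on simulated data with 10 draws of random noise on the observed means and 200 genes changed by a log2 of 1 or 2. With each probe set keeping its moderated variance from the fit, the BMP4 fit across times recovered 55.4% of the genes changed by 1 and 98.8% of those changed by 2, and 8.2% of its calls were false. The false share was then 9.3% for BMP4 at 12 h, 13.6% at 3 h, 10.4% at 24 h and 19% for the change between times. It was 13.8% for untreated culture at 24 h and 8.7% for culture time over both agents. These shares exceed the nominal 5%. With variances drawn from limma's fitted prior, the false shares ran from 0% to 6%, and the recovery was lower. In the comparison at 24 h, 54% of the genes changed by 2 were recovered in the first simulation and 16.3% in the second. Both simulations give all arrays of a probe set the same spread. They therefore do not test whether lone arrays vary like the 12 h samples. With 1 simulated list shifted by 0.5, camera at the preset correlation called that list and 0 of the others. The simulated genes were independent, so this does not test calls among correlated genes. Camera with an estimated correlation was not simulated.

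The alternatives tried were other pseudocounts, quantile normalisation, median centring, no filter, a stricter filter, variances without the trend, an adjusted p under 0.10, 1 test per gene, and the mean of a gene's probe sets. Arrays and times were also left out in turn, the 3 times were weighted equally, and the letters A and B were used as a block. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.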

Results

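The data are 9 expression arrays of chick splanchnic mesoderm explants from the anterior heart field. Single arrays cover untreated explants at 0, 3 and 24 h and BMP4-treated explants at 3 and 24 h, and 2 arrays cover each arm at 12 h. The 2% trimmed mean signal per array was 503.66 to 504.72 and the median signal 67.17 to 67.67. Across probe sets, log2 signals of the 12 h pair correlated with r = 0.970 untreated and r = 0.972 with BMP4. The BMP4 24 h array correlated with the others at 0.930 to 0.964 and the untreated 0 h array at 0.930 to 0.962, the lowest value being that between these 2. The 3′ to 5′ signal ratio of the ACTB control probe sets, a sign of RNA integrity, ran from 3.72 in the untreated 24 h array to 5.67 in the BMP4 24 h array. The ACTB ratio was higher with BMP4 at every time: 4.96 against 4.51 at 3 h, and 5.50 against 5.44 (A) and 4.26 against 3.80 (B) at 12 h. Whether it bears on the differences across times was not tested. The GAPDH ratio ran from 1.32 to 2.22, and was higher with BMP4 in 12 h A and at 24 h and lower at 3 h and in 12 h B. No value other than those at 12 h has replicates.

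Over 3, 12 and 24 h, 7 of 28 BMP targets and 13 of 35 sarcomere genes were called higher in BMP4-treated than in untreated explants, and 10 of 27 FGF and ERK feedback genes lower. When any 1 of the 12 h arrays was left out, these counts were 5 for BMP targets, 6 to 10 for sarcomere genes and 3 to 5 for FGF genes. The list calls were lost at an adjusted p = 0.104, 0.181 and 0.181 with an estimated correlation, a test with 4 degrees of freedom here. The 3 h arrays alone gave no call among the FGF or sarcomere genes. MSX2, a homeobox gene induced by BMP, was 3.65-fold higher (log2 1.87 ± 0.10, adjusted p = 6.6e-07) and differed alike at 3 h (1.92), 12 h (1.72) and 24 h (2.10). MYH7B, a myosin heavy chain, was 3.03-fold higher (1.60 ± 0.19, adjusted p = 0.00157). FGF19 was 7.67-fold lower (−2.94 ± 0.42, adjusted p = 0.00385) and FGF3 6.57-fold lower (−2.72 ± 0.31, adjusted p = 0.00103). This comparison asks how BMP4-treated explants differ from untreated ones whatever the time, with the 12 h arrays weighing most. In it limma called 340 of 28329 probe sets, 209 higher and 131 lower, or 134 and 83 named genes. All but a few of them, 333 of the 340, had the same sign at each of the 3 times. This share is no separate evidence, since the fit counts differences between the times as spread and the signs come from the same arrays.

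The genes with the highest increases were LOC417741 (2.92 ± 0.13, adjusted p = 2.48e-07), the potassium channel regulator ABCC9 (2.66 ± 0.35) and RGS4, which damps G protein signaling (2.45 ± 0.34). They were followed by the transcription factor SOX14 (2.17), FIBIN (1.93), the hyaluronan receptor CD44 (1.89), the transcription factor BHLHE22 (1.88) and MSX2. EPAS1 (2.13) was called higher as well but lies outside this order, without the same sign at the 3 times. SAMD11, IL13RA2, the cartilage and valve regulator SOX9, PKDCCB, MYH7B, TMEM37 and the proteoglycan GPC3 rose by 1.54 to 1.86. The lowest among called genes with the same sign at the 3 times were FGF19, FGF3, C1QL3 (−2.16 ± 0.38), FAM163B (−2.02), EYA2, a transcriptional cofactor of progenitor cells (−1.97 ± 0.35), and RSPO3, an enhancer of Wnt signaling (−1.97 ± 0.26). FGF8, given below, was called lower as well but lies outside this order, with 0.21 at 3 h. VEGFD, FGF18, BPIFB2, the Notch target HES5, CYP26C1, which degrades retinoic acid, GBX2, ISL2, PDGFA and DLX1 fell by between −1.66 and −1.96 on the log2 scale. For C1QL3, DLX1, IL13RA2, SAMD11 and SMAD7, and for FZD8, LGALS3, SFRP1 and UNC45B among the list members below, the probe sets of the gene differed in sign. With 1 sign, probe sets still ran from 0.33 to 2.92 for LOC417741, 0.28 to 1.89 for CD44 and 0.61 to 1.93 for FIBIN. Of the list members below, those of FGFR3 ran from 0.31 to 1.34 and those of MYBPC3 from 0.40 to 1.46. They were close for FGF3 (−2.93 and −2.72), RSPO3 (−1.97 and −1.82), CYP26C1 and PDGFA. On assembly GRCg7b, MSX2 lies on chromosome 13 from 9409592 to 9415374, FGF3 on chromosome 5 from 17174173 to 17180800, and MYH7B on chromosome 20 from 2960228 to 2986540.

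Of 28 measured BMP targets and feedback genes, 7 rose and none fell (13 and 2 adjusted over the list alone, 6 and 2 without the 3 h pair), with a median log2 difference of 0.42. The feedback inhibitors BAMBI (1.11 ± 0.08), SMAD7 (1.15 ± 0.24) and SMAD6 (0.54 ± 0.07) were among them, with BMPER, DLX5, ID4 and MSX2. The direct BMP targets ID1 (0.33 ± 0.15), ID2 (0.14), ID3 (0.39) and MSX1 (0.62) did not pass the test. The list's camera call (adjusted p = 6.98e-09) was lost at an adjusted p = 0.104 with an estimated correlation. Of 27 FGF and ERK feedback genes, 10 fell and 1 rose (15 and 2 adjusted over the list alone), with a median of −0.41. Those that fell were FGF3, FGF8 (−2.08 ± 0.43), FGF18, FGF19, the feedback inhibitors SPRY1 (−1.37 ± 0.22), DUSP4, DUSP5, DUSP6 (−0.77 ± 0.17) and IL17RD (−1.47 ± 0.32), and the ERK-responsive factor ETV4 (−0.92 ± 0.17). The receptor FGFR3 rose by 1.34 ± 0.25, while SPRY2 (−0.57), ETV5 (−0.32), FGF10 (−0.71) and FGFR1 (−0.13) did not pass the test. The camera call (adjusted p = 9.48e-09) was lost at an adjusted p = 0.181 with an estimated correlation.

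**Figure D1:**
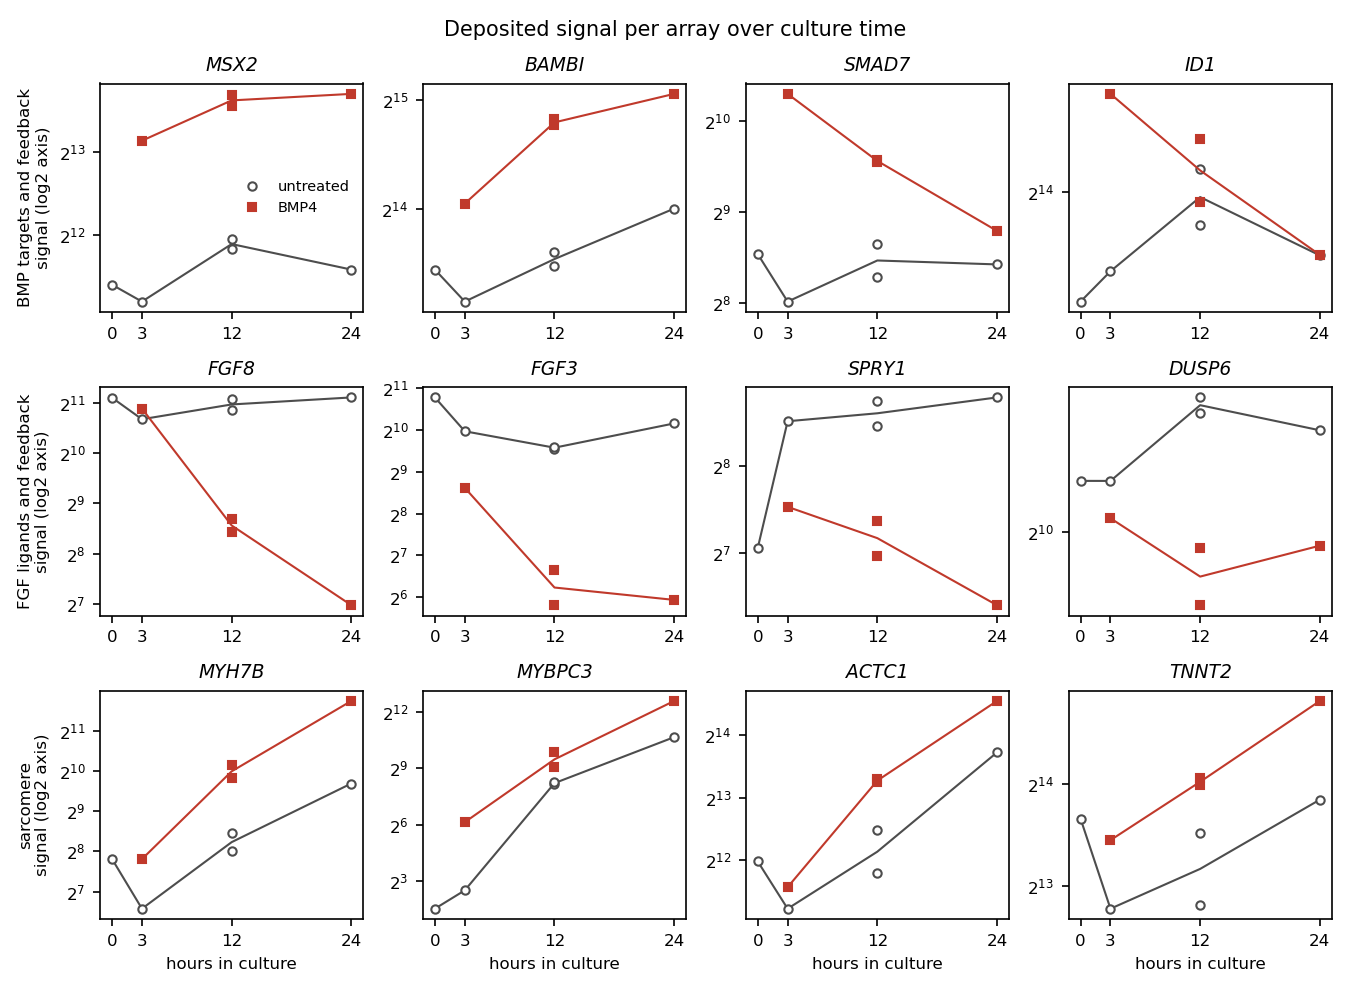
Deposited signal per array (log2 axis, range differing between panels) against hours in culture for 12 genes, with circles for untreated and squares for BMP4 arrays and lines through the geometric mean per time. MSX2 signals were 8980 to 13266 with BMP4 against 2348 to 3944 without, and FGF8 signals with BMP4 were 1895 at 3 h and 126 at 24 h.

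Of 35 cardiomyocyte sarcomere and calcium genes, 13 rose and none fell (20 and 0 adjusted over the list alone), with a median of 0.67. They include the thick filament proteins MYH7B and MYBPC3 (1.46 ± 0.21), the thin filament proteins ACTC1 (0.86 ± 0.15) and TNNT2 (0.83 ± 0.12), the ventricular light chain MYL2 (1.02 ± 0.14), and the Z-disc protein ACTN2 (1.24 ± 0.28). CSRP3, HSPB7, MYL4, POPDC2, SMPX, TNNI1 and UNC45B rose as well, while MYH7 (0.52) and MYH15 (0.67) did not pass the test. The camera call (adjusted p = 4.63e-18) was lost at an adjusted p = 0.181 with an estimated correlation. Of 25 cardiac transcription factors, 4 rose and none fell (11 and 1 adjusted over the list alone): GATA5 (0.89 ± 0.09), HAND2 (0.92 ± 0.18), MYOCD (1.05 ± 0.23) and SMYD1 (1.19 ± 0.23). NKX2-5 (0.44), GATA4 (−0.02), TBX5 (0.33) and HAND1 (1.09) did not pass the test. That list's camera call (adjusted p = 7.82e-05) was lost at an adjusted p = 0.104 with an estimated correlation. Of 20 anterior heart field progenitor genes, EYA2, FGF8 and FOXC2 (−1.17 ± 0.23) fell and ISL1 rose (0.53 ± 0.09), or 6 and 2 adjusted over the list alone. TBX1 was at −0.66 ± 0.24, TCF21 at 0.09 and MYF5 at −0.54, none past the test. The camera call (adjusted p = 0.00717, median −0.25) was lost at an adjusted p = 0.29 with an estimated correlation.

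The median of 35 cell cycle genes was −0.34, and 34 had a negative sign, while the median was −0.03 at 3 h alone. MCM2 (−0.68 ± 0.11) and RRM2 (−0.65 ± 0.09), both needed for DNA replication, fell over all probe sets tested, 19 fell adjusted over the list alone, and 11 fell without the 3 h pair. The camera call (adjusted p = 5.93e-16) was lost at an adjusted p = 0.181 with an estimated correlation. Among 20 cell cycle arrest and apoptosis genes, BTG2, an inhibitor of proliferation, rose by 0.83 ± 0.15 (5 adjusted over the list alone), and the camera adjusted p = 0.0173 became an adjusted p = 0.266 with an estimated correlation. HES5 (−1.81 ± 0.26) fell among 13 Notch genes (5 adjusted over the list alone), whose median of −0.24 had an adjusted p = 0.000848 by camera and an adjusted p = 0.151 with an estimated correlation. CYP26C1 (−1.80 ± 0.17) fell among 15 retinoic acid genes (4 adjusted over the list alone), with an adjusted p = 0.0173 by camera and an adjusted p = 0.181 with an estimated correlation. Of 29 Wnt genes, WNT3A (1.43 ± 0.20) rose and RSPO3, FZD8 and SFRP1 fell (3 and 7 adjusted over the list alone), and camera gave no call (adjusted p = 0.118).

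In markers of other tissues the explants could hold, calls went both ways. In pharyngeal endoderm and epithelium HHEX rose (1.09 ± 0.14) and SOX3 fell (−1.22 ± 0.23) among 20 genes. In neural tissue SOX3 alone fell among 14. In neural crest DLX5, HAND2, PRRX1 (1.02 ± 0.11) and SOX9 rose and DLX1 fell among 19. In limb, arch and outflow mesenchyme MSX2, PRRX1 and SOX9 rose among 21, and in skeletal muscle the actin ACTA1 (0.78 ± 0.15) rose among 12. Adjusted over the list alone, 6 rose and 3 fell in the endoderm list, 1 and 3 in neural tissue, 5 and 2 in neural crest, 6 and 0 in mesenchyme, and 1 and 0 in skeletal muscle. None passed among 12 smooth muscle, 22 endothelial, 14 blood or 29 matrix genes, with 0, 0, 2 and 5 higher and 0, 0, 0 and 2 lower adjusted over the list alone. SLC2A1 (−0.62 ± 0.13), a glucose transporter, fell among 28 glycolysis and hypoxia genes, and CD44 and LGALS3 (0.92 ± 0.12) rose among 26 interferon and inflammation genes. None of 18 sterol synthesis, 8 hedgehog or 21 immediate early and heat shock genes passed. Adjusted over the list alone, 1 glycolysis, 1 hedgehog and 1 immediate early gene fell, 2 inflammation genes rose and 2 fell, and no sterol synthesis gene passed. Camera also called mesenchyme (adjusted p = 0.00717), neural tissue (0.0173), smooth muscle (0.0209) and sterol synthesis (0.00952). These were lost at an adjusted p = 0.175, 0.266, 0.181 and 0.266 with an estimated correlation, and no list in any comparison kept its call. That test has 4 or 2 degrees of freedom, so few lists could pass it. Fry called the BMP target, cardiac transcription factor (both adjusted p = 0.0148), mesenchyme, Notch and retinoic acid lists. The medians of the blood, neural crest and matrix lists were below 0 while camera's direction was up, and that of the immediate early list above 0 while camera's was down, none of them called.

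The test was limma's, with time as a factor. The number of calls rests on the variance trend over signal: without it 4 probe sets were called (2806 had an unadjusted p under 0.05), those of MSX2, BHLHE22 and 2 of LOC417741. Without the 12 h pairs 9 were called, without the 24 h pair 146, without the 3 h pair 591, leaving out any 1 of the 12 h arrays 147 to 218, and with an adjusted p under 0.10 542. With the mean of a gene's probe sets 130 genes were called, against 217.

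At 12 h, the replicated time, BMP4-treated explants had less RNA of some FGF ligands and more of a set of regulators and myosins than untreated ones. FGF3 (−2.93 ± 0.27), FGF19 (−2.79 ± 0.25) and FGF8 (−2.33 ± 0.21) fell, as did RSPO3 (−2.61), FAM163B, NTNG2, AADACL3C and EYA2 (−2.12). TH, the rate-limiting enzyme of catecholamine synthesis, rose (adjusted p = 0.000781), with signals of 557 and 596 against 4.7 and 8.7, and its log2 difference of 4.13 depends on the 27.79 added, as do those of FAM163B, SOX14 and CD44. BRINP3 (3.95), SOX14 (3.19), RGS4, ABCC9, LOC417741, the hypoxia-responsive factor EPAS1 (2.81 ± 0.27) and SOX9 (2.71) rose as well. BAMBI (1.25), MSX2, BMPER (1.88), DLX5 and SMAD6 rose among BMP targets, and ACTC1 (1.14), MYH15 (1.13), MYH7B, MYL2 (1.31) and MYL4 (1.22) among sarcomere genes. For NTNG2 and FZD8 the probe sets of the gene differed in sign.

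In this comparison of 2 arrays with 2, 174 probe sets were called, 110 higher and 64 lower, or 71 higher and 81 lower without BMP4 array A. Of the BMP targets 5 rose and none fell (11 and 2 adjusted over the list alone). Of the FGF and ERK feedback genes 6 fell and FGFR3 rose (12 and 1 adjusted over the list alone). Of the sarcomere genes 5 rose (18 adjusted over the list alone), and of the cell cycle genes RRM2 fell (12 adjusted over the list alone), all 35 having a negative sign. The respective medians were 0.51, −0.47, 0.78 and −0.33, and the camera calls gave adjusted p = 0.257, 0.257, 0.277 and 0.257 with an estimated correlation. Of the anterior heart field genes EYA2 and FGF8 fell (4, and 1 higher, adjusted over the list alone), and of the cardiac transcription factors GATA5 rose (8, and 1 lower, adjusted over the list alone), both lists at an adjusted p = 0.257 with an estimated correlation. PAX6 (−2.06) fell in neural tissue, HES5 (−1.66) in Notch and CYP26C1 (−1.67) in retinoic acid, and HHEX (1.22) rose in endoderm. Camera also called neural tissue, neural crest, mesenchyme, arrest and apoptosis, Notch, retinoic acid and sterol synthesis, at an adjusted p = 0.257 to 0.418 with an estimated correlation. SPRY1 (−1.27 ± 0.28), DUSP6 (−1.06), ETV4 (−1.09), TNNT2 (0.85) and HAND1 (2.0) did not pass the test at this time alone. Without the variance trend 0 were called by limma (2339 with an unadjusted p under 0.05), without the filter 86, without untreated array A 99, with an adjusted p under 0.10 323, and with A and B as a block 1106.

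At 3 h, when each arm has 1 array, few genes were called. MSX2 (1.92 ± 0.19, adjusted p = 0.0123), LOC417741 (3.44 ± 0.20) and FAM132A (2.24 ± 0.23) were the called genes, all higher, with 4 probe sets in all. SMAD7 (2.17 ± 0.34), ID1 (1.01 ± 0.21), MSX1 (1.12 ± 0.27), BAMBI (0.90 ± 0.14) and ISL1 (0.76 ± 0.18) were higher without passing the test. FGF8 differed by 0.21 ± 0.29 and SPRY1 by −0.88 ± 0.39. Other wide differences that did not pass, all of them in 1 array against 1, were FEV (−2.91), GLIPR1L (−2.88), SLC25A39 (−2.79), SAMD11 (2.39) and OC90 (2.38).

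Adjusted over the list alone, 9 BMP targets rose, with a median of 0.28, and the camera call (adjusted p = 9.82e-10) had an adjusted p = 0.456 with an estimated correlation. None of 27 FGF and ERK feedback, 35 sarcomere or 35 cell cycle genes passed, over all probe sets or adjusted over the list alone, and their medians were −0.11, 0.12 and −0.03. Camera called the sarcomere list (adjusted p = 0.00822), cardiac transcription factors (0.00255, median 0.31) and Notch (0.0208, median −0.29, 12 of 13 negative). These calls had an adjusted p = 0.757, 0.456 and 0.566 with an estimated correlation. In limb, arch and outflow mesenchyme MSX2 rose (4 adjusted over the list alone), and the camera call (adjusted p = 0.000241) had an adjusted p = 0.456 with an estimated correlation. At an unadjusted p under 0.05 there were 1212 probe sets. Without the variance trend 0 were called by limma (1564 with an unadjusted p under 0.05), and leaving out any 1 of the 12 h arrays, which alters only the spread, gave 8 to 11, and A and B as a block 115.

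At 24 h, 8 of 27 FGF and ERK feedback genes and 4 of 13 Notch genes fell with BMP4, and 4 of 35 sarcomere genes rose. PAX6, a regulator of eye and neural development, fell (adjusted p = 0.000599), with a signal of 6.9 against 1451, and its log2 difference of −5.41 depends on the 27.79 added. ZPLD1 (−5.28), FGF19 (−5.04 ± 0.35), FOXI2 (−4.87), LOC419390 (−4.54), the neuropeptide NPY (−4.38 ± 0.25), the retinoic acid binding protein CRABP1 (−4.30) and FGF8 (−3.87 ± 0.29) fell as well. The highest were PRPS2, a nucleotide synthesis enzyme (4.60 ± 0.43), ALPPL, an alkaline phosphatase (4.27 ± 0.42), ABCC9 (3.89), RGS4 (3.06), EPAS1 (2.99), FIBIN (2.93), RGS18 and SELENOP1. ACTN2 (2.17 ± 0.40), SMPX (2.07), MYH7B (2.02) and the calcium pump ATP2A2 (1.33) rose among sarcomere genes. For ATP2A2 and HES5 the probe sets of the gene differed in sign.

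Limma called 204 probe sets, 78 higher and 126 lower. Of the FGF and ERK feedback genes 8 fell and FGFR3 rose (13 and 2 adjusted over the list alone), with CCND1 (−1.71), DUSP4, IL17RD (−3.02) and SPRY2 (−1.38) beside the 4 ligands. In Notch DLL1 (−1.80), HES5 (−2.76), HES6 (−2.76) and HEY1 (−1.37) fell (5 adjusted over the list alone, where 1 rose). In neural tissue PAX6 and SOX3 fell (4 and, higher, 1 adjusted over the list alone). Of the sarcomere genes 4 rose (21 adjusted over the list alone) and of the cell cycle genes CDCA3 fell (−1.05 ± 0.16; 23 adjusted over the list alone). The medians of these lists were −0.79, −0.44, −0.46, 0.95 and −0.75, and each call of camera had an adjusted p = 0.267 with an estimated correlation. BMP targets were split: MSX2 (2.10) and BAMBI (1.05) rose and HEY1 and the BMP antagonist SOSTDC1 (−2.11 ± 0.34) fell (5 and 4 adjusted over the list alone). Of the anterior heart field genes EYA2 (−3.47) and FGF8 fell (7, and 2 higher, adjusted over the list alone), with an adjusted p = 0.267 with an estimated correlation. TBX5 (2.50 ± 0.52), MYH7 (2.24 ± 0.50) and SPRY1 (−2.05 ± 0.39) did not pass the test. Camera also called cardiac transcription factors, skeletal and smooth muscle, arrest and apoptosis, Wnt, hedgehog, retinoic acid, glycolysis and sterol synthesis, at an adjusted p = 0.267 to 0.336 with an estimated correlation.

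In the endoderm and epithelium list HHEX (1.50), KRT7 (0.96) and KRT24 (0.78), which stands for the listed KRT19, rose and PAX9 (−1.91) and SOX3 fell (5 and 2 adjusted over the list alone). The 2 arrays compared here also have the highest and the lowest ACTB 3′ to 5′ ratio of the 9, as given above. Each arm has 1 array, and no replicate stands behind these differences. Without the variance trend 0 were called by limma (2800 with an unadjusted p under 0.05), without the filter 80, leaving out any 1 of the 12 h arrays gave 360 to 367, an adjusted p under 0.10 406, and A and B as a block 1367.

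**Figure D2:**
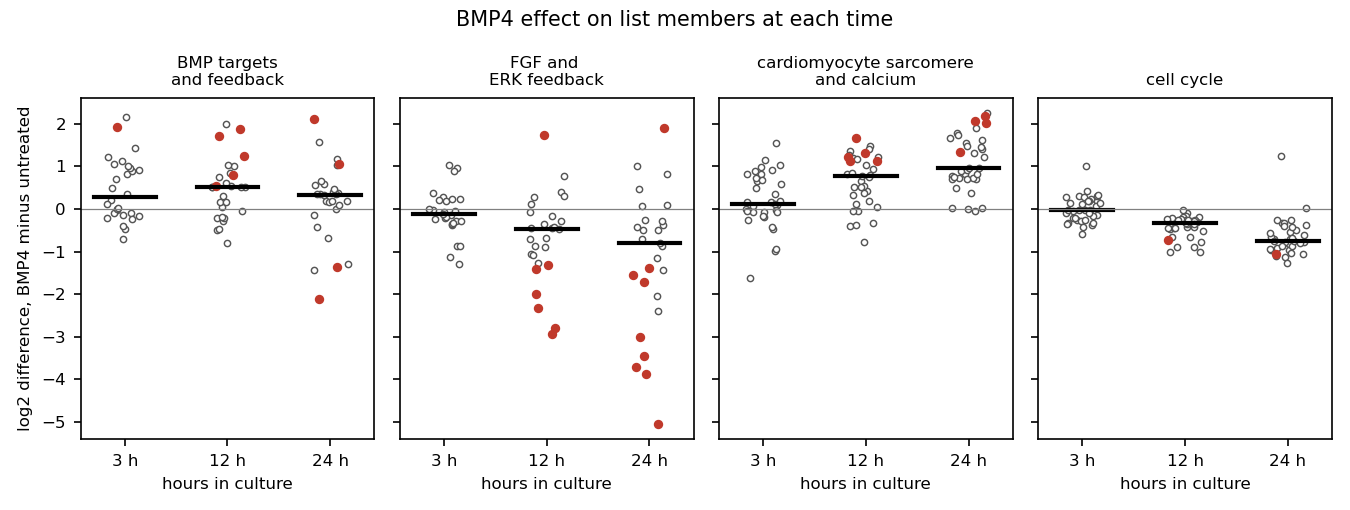
BMP4 minus untreated log2 difference of each measured member (points, filled where called) of 4 gene lists at 3, 12 and 24 h, with bars at the medians. The FGF and ERK feedback medians were −0.11, −0.47 and −0.79 and the sarcomere medians 0.12, 0.78 and 0.95 at the 3 times.

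Between 3 h and 24 h the BMP4 effect itself differed for 15 genes, 12 of them turning lower. FGF8 went from 0.21 at 3 h to −3.87 at 24 h, a change of −4.08 ± 0.41 (adjusted p = 0.0152), and ZPLD1, PAX6, NPY and LOC419390 changed by −6.65 ± 0.68, −5.13 ± 0.62, −4.26 ± 0.35 and −4.17 ± 0.48. The sizes for PAX6 and ZPLD1, each with a signal under 27.79 in 1 array, depend on that amount. PRPS2 (4.88 ± 0.61), ALPPL (4.44 ± 0.59) and SNTB1 (2.71 ± 0.38), a dystrophin-associated protein, changed upward. In this interaction 17 probe sets were called, 4 upward and 13 downward. Of the FGF and ERK feedback genes FGF8, FGF18 and FGF19 changed downward (10, and 1 upward, adjusted over the list alone), with a median of −1.02 and an adjusted p = 0.363 with an estimated correlation. The effect on MSX2 (0.18 ± 0.27), ID1 (−1.01 ± 0.29) and SMAD7 (−1.83 ± 0.48) was not shown to differ between the times. Without the variance trend 0 were called by limma (2021 with an unadjusted p under 0.05), without the filter 1, leaving out any 1 of the 12 h arrays 52 to 59, with an adjusted p under 0.10 38, and with A and B as a block 612, of which 379 were downward. With 1 test per gene 28 genes were called, against 15.

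The BMP4 effects at 12 h and 24 h, which come from separate arrays, were alike among the genes that had changed. Across the 120 genes called at 12 h, the log2 differences had r = 0.852 with those at 24 h and 99.2% had the same sign. Against 3 h the values were r = 0.564 and 83.3%. Across the 142 genes called at 24 h, r was 0.838 with 12 h and 0.388 with 3 h. Over all 11675 genes r was 0.373 for 12 h with 24 h, 0.131 for 3 h with 12 h, and 0.053 for 3 h with 24 h, against 0.352 between the A and B pairs at 12 h. These are correlations across genes, which are not independent replicates.

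Muscle genes also rose over time in culture without BMP4: by 24 h 13 of 35 sarcomere genes and 5 of 21 immediate early and heat shock genes had risen in untreated explants since 0 h, with an adjusted p = 0.276 for each list with an estimated correlation. MYBPC3 (5.72 ± 0.43), MYL1 (4.70 ± 0.66), CSRP3 (4.02), MYL3 (3.90), MYL2 (3.28) and ACTC1 (1.74) rose, while TNNT2 (0.19 ± 0.27) did not pass the test. Other genes that rose were ZPLD1 (6.18), ETNPPL (5.57), the cyclin-dependent kinase inhibitor CDKN2B (5.55 ± 0.28), IL15 (4.61), NPY (4.43) and ASTL (4.42). C18orf8 (−3.73), the fibrinogen chain FGB (−3.55), ANO3, LRRC32, LOC770996, SHC2, the BMP and Nodal antagonist CER1 (−2.82) and B3GALNT2 fell. The sizes for CER1, DLX1, ETNPPL, HMOX1, IL15, KLHL41, LOC770996, MYBPC3, SOX9 and ZPLD1 depend on the 27.79 added, since 1 of the 2 signals was lower than that, and the probe sets of B3GALNT2, C18orf8 and SHC2 differed in sign. Neural crest genes SOX10 (−2.59), FOXD3 (−2.48) and SOX8 (−1.82) fell and SOX9 (2.86), DLX1, DLX5 and TFAP2B rose (5 and 6 adjusted over the list alone).

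In this comparison of 1 array with 1, untreated explants at 24 h against 0 h, 458 probe sets were called, 339 higher and 119 lower. No uncultured tissue of a later time was measured, so culture and 24 h of development cannot be told apart. Of the sarcomere genes 13 rose and none fell (22 and 2 adjusted over the list alone), with a median of 1.25 and an adjusted p = 0.276 with an estimated correlation. Skeletal muscle genes MYL1, KLHL41 (2.70) and ACTA1 (2.43) rose, and glycolysis genes LDHA (2.91), PFKP (1.40) and PGK2 rose (3 and 11 adjusted over each list alone). Heat shock and immediate early genes HSPB1 (3.95), HMOX1 (2.52), KLF2 (2.11), KLF6 and JUN rose (6 adjusted over the list alone), and so did sterol synthesis genes FDPS, FDFT1 and INSIG1 (8 adjusted over the list alone). No FGF and ERK feedback gene of 27 passed (3 higher and 1 lower adjusted over the list alone), FGF8 differing by 0.01 ± 0.29. Against 0 h, 271 probe sets were called at 12 h (224 higher) and 93 at 3 h (88 higher). At 3 h CDKN2B (5.42), the matrix protease MMP9 (5.12), the chemokine IL8L2 (4.96), PSPH (4.84), IRF1 (4.70), CHAC1 (4.57), the activity-regulated gene ARC (4.31) and CCNA1 (4.26) rose, and BOD1L1, LOC417741 (−1.37) and TXNDC17 fell. At 12 h CDKN2B (6.17), ETNPPL (4.69), ZPLD1 (4.57), IL15 (4.55) and IL8L2 (4.54) rose, and LRRC32 (−3.19), SCGN (−2.85), ZIC2 (−2.51) and the endothelin receptor EDNRB (−2.21) fell. At 12 h 8 of 18 sterol synthesis genes rose (16 adjusted over the list alone), FDFT1 by 2.07 and HMGCS1 by 1.62, with a median of 1.18 and an adjusted p = 0.254 with an estimated correlation. The 3 comparisons share the 0 h array, in which ARC, ETNPPL, IL15, IL8L2, MMP9 and ZPLD1 had signals under 27.79, and for ARC, LRRC32, PSPH and TXNDC17 the probe sets of the gene differed in sign. Without the variance trend 0 were called at 24 h by limma (3402 with an unadjusted p under 0.05), without the filter 248, with an adjusted p under 0.10 833, and with A and B as a block 2250.

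From 3 h to 24 h of culture, over both agents, 22 of 35 sarcomere genes and 5 of 22 endothelial genes rose. MYL1 (6.41 ± 0.57), MYBPC3 (5.78 ± 0.30), MYL3 (4.91), MYL2 (4.13), MYH15 (3.51) and MYH7B (3.28) rose, with the adhesion molecule VCAM1 (4.78), ANXA8L1, EEF1A2 and the neurofilament NEFM (3.97). CER1 (−4.09 ± 0.34), TSPAN1, IRF1 (−3.55), CHAC1 (−3.47), CCL17, PSPH (−3.10), C18orf8 and GBX2 (−3.07) fell. The sizes for CER1, MYL1 and VCAM1 depend on the 27.79 added, and for C18orf8, EGFL7 and KDR the probe sets of the gene differed in sign. Of the sarcomere genes 22 rose and none fell (25 and 1 adjusted over the list alone), with a median of 2.0. Among endothelial genes CDH5 (1.32), EGFL7, FLI1, the VEGF receptor KDR (2.08 ± 0.26) and TEK (1.89) rose and none fell (6 adjusted over the list alone). Of the glycolysis genes 11 rose and NDRG1 fell (12 and 3 adjusted over the list alone), LDHA by 3.12 ± 0.22, and of the cell cycle genes 7 fell (8, and 1 higher, adjusted over the list alone). TBX1 (−1.30 ± 0.34) and TCF21 (−0.97 ± 0.26), regulators of pharyngeal mesoderm, fell, and NKX2-5 (−0.71 ± 0.22) did not pass the test.

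Limma called 1868 probe sets, 1054 higher and 814 lower, from 2 arrays against 2. The camera calls of the sarcomere, endothelium, glycolysis and cell cycle lists had an adjusted p = 0.306, 0.237, 0.306 and 0.533 with an estimated correlation. Without the variance trend 429 were called, and with an adjusted p under 0.10 the count was 2923.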

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

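The tests of a fault in 1 array, of epithelial and placodal markers and of lists of matched signal were chosen after the results were seen, while those of the change between times, of the gene lists and of the splits of the arrays were planned.

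The effect of BMP4 differed between 3 h and 24 h by a test of the difference itself for 17 probe sets. By gene, the change in log2 difference was −6.65 for ZPLD1, −5.13 for PAX6, −4.26 for NPY, −4.17 for LOC419390, −4.08 for FGF8, −3.91 for FGF19, −3.53 for C2orf40 and −3.29 for EYA2. It was −3.25 for CYTL1, −3.12 for FGF18, −2.89 for VEGFD and −2.43 for CA9, and upward 2.71 for SNTB1, 4.44 for ALPPL and 4.88 for PRPS2. Of the gene lists, limma's camera at the preset correlation called a change between the times for BMP targets (median −0.20), FGF and ERK feedback (−1.02), anterior heart field progenitors (−0.56), sarcomere and calcium (0.78), neural tissue (−0.79) and cell cycle (−0.69). It also called arrest and apoptosis (0.29), Notch (−0.29), hedgehog (−0.60), glycolysis and hypoxia (−0.13) and sterol synthesis (−0.28). None of these list calls held with an estimated correlation and its 2 degrees of freedom, where the adjusted p ran from 0.363 to 0.415. Each of these differences rests on 1 array per arm at each time.

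For the genes far lower with BMP4 in the single array at 24 h, FGF ligands and PAX6 among them, a fault of that array alone is argued against by the 12 h pairs: 84.6% of the 91 genes called lower at 24 h were lower in both pairs, against 30.7% of all genes, and 22 of the 91 were called lower at 12 h with 0.312 expected by chance and 0 called higher. Genes that move together are not independent, so the share carries no interval, and for the genes not called at 12 h a fault stays open when they are taken singly. The 0.312 assumes independent calls, while both tests use the spread of the 12 h arrays, so it can be too low. For epithelium as a whole, a loss that would bring its markers to a median of −1 or lower is argued against in these 2 arrays. The markers of surface ectoderm and general epithelium had a median of 0.18 with a standard error of 0.23 across the 18 genes. That error takes genes of 1 array against 1 as replicates and holds no variation between explants. The −1 was set after the results were seen, and a smaller loss stays open. Many of these markers are shared with endoderm, so a loss of ectoderm alone stays open, as does the difference in ACTB 3′ to 5′ ratio between these 2 arrays, which was not tested. That ratio was higher with BMP4 in both 12 h pairs as well, so the 12 h pairs do not settle it. Fewer placodal or anterior neural cells and a lower expression in the same cells cannot be told apart. The 10 markers of that list outside the named genes and the called members of other lists had a median of −0.70 with a standard error across genes of 0.56. Leaving out members named or called for their change can pull this median toward 0, so it cannot decide. Of the 10, 7 were below 0, SIX3 (−3.31) being the lowest, and OTX2, which endoderm also expresses, was at −0.03.

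The median of the cell cycle genes with BMP4 was −0.34 across the times, with 2 of 35 past the test, and −0.03 at 3 h, −0.33 at 12 h and −0.75 at 24 h. A shift of bright probe sets, as scaling by intensity would give, is argued against: 0% of 10000 random lists of matched signal had a median as extreme as −0.34, the random medians lying between −0.10 and 0.07. Slower division of the same cells and a different mix of cells remain open, and no biological explanation was tested. For the list as a whole, the call was lost at an adjusted p = 0.181 with an estimated correlation and its 4 degrees of freedom.

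Of the sarcomere and calcium genes 13 of 35 rose with BMP4 across the times, and the medians were 0.12 at 3 h, 0.78 at 12 h and 0.95 at 24 h. The same shift is argued against here as well, with 0% of 10000 matched lists reaching the median of 0.67 and random medians between −0.12 and 0.11. An earlier or stronger differentiation and a higher share of cells that had already begun it both remain open. Of 34 splits of the 8 cultured arrays, 1, the real one, gave as many as 340 called probe sets and the highest of the others 3, while at an unadjusted p under 0.05 the real one had 2959 and the others up to 2759. Some of these splits are the same contrast once time is a factor. In the splits other than the real one the BMP4 effect counts as spread, which lowers their number of calls. The agents are matched by time, so the real split can be set only against the 12 balanced over the times, which are too few for a share under 5% and of which the others gave 0 by limma (804 to 2395 unadjusted), and the medians of the lists were not run over the splits.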

How the results depend on the processing

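The calls rest on limma's variance trend over signal. Without it 4 probe sets were called for BMP4 across times, 0 at 12 h, 0 at 3 h, 0 at 24 h, 0 for the change between times, 0 for untreated culture at 24 h and 429 for culture time over both agents. At an unadjusted p under 0.05 limma then had 2806, 2339, 1564, 2800, 2021, 3402 and 5196. With an adjusted p under 0.10 the counts were 542 across times, 323 at 12 h, 406 at 24 h, 38 for the change, 833 for untreated culture and 2923 for culture time. Without the filter more probe sets enter the adjustment, and the counts were 86 at 12 h, 80 at 24 h, 1 for the change and 248 for untreated culture. Counted in genes, of which 217 were called across times and 15 for the change, 1 test per gene gave 226 and 28, and the mean of a gene's probe sets gave 130 across times. Leaving out the 3 h pair gave 591 calls across times, leaving out the 12 h pairs 9 and leaving out the 24 h pair 146. Leaving out 1 of the 12 h arrays at a time gave 147 to 218 across times, 99 to 187 at 12 h, 8 to 11 at 3 h, 360 to 367 at 24 h and 52 to 59 for the change. A lone array was then assumed to vary like the other groups. For the variance trend, the mean of probe sets and the arrays left out, the cause was not tested.

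The labels do not say what arrays with the same letter share. The ACTB 3′ to 5′ ratio was 5.44 and 5.50 in the A arrays and 3.80 and 4.26 in the B arrays. Across arms, arrays with the same letter correlated at r = 0.966 (A) and 0.969 (B), and those with different letters at 0.962 and 0.966. A pairing or batch behind the letters stays open, and the fits above do not allow for it. As a replicate block the letters leave 1 residual degree of freedom in the group-means fit. With this pairing the counts were 1106 at 12 h, 115 at 3 h, 1367 at 24 h, 612 for the change and 2250 for untreated culture, and 295 across times. The deviations of A from B correlated across genes with r = 0.169 between the arms.

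No named gene that passed the test changed direction, untreated culture at 3 h and 12 h not having been rerun. Of the lists with a camera call, that of mesenchyme did, its median across times going from 0.05 to −0.04 without the 3 h pair, where the call was lost (adjusted p = 0.0781). The calls at 12 h went from 110 higher and 64 lower to 71 higher and 81 lower without BMP4 array A. Over all alternatives, 6581 values of named genes kept their side of the threshold, 796 no longer passed and 74 passed newly, and for the other lists the numbers were 324, 14 and 2. The medians of the BMP, FGF, sarcomere and cell cycle lists across times kept their sign and their camera call at the preset correlation under each alternative run for them, which leaves out the adjusted p under 0.10 and the 1 test per gene. They ran from 0.33 to 0.46 for BMP targets, from −0.31 to −0.63 for FGF, from 0.60 to 0.85 for sarcomere and from −0.24 to −0.47 for cell cycle genes, the ends of the last 3 being those without the 24 h pair and without the 3 h pair. In a count of list members chosen after the data had been seen, 1 to 8 BMP targets rose and 0 to 2 fell, 0 to 11 FGF genes fell, 0 to 16 sarcomere genes rose and 0 to 11 cell cycle genes fell. Of the 74 named genes called across times, 43 to 55 were still called when a 12 h array was left out, 65 with the block, 6 without the 12 h pairs and 3 without the trend, and all 74 kept their sign. Signals under the added 27.79 limit what can be measured of weakly expressed genes: with the 5th percentile or the median added, the difference of TH at 12 h was 5.22 or 3.12 and that of PAX6 at 24 h −6.51 or −4.35.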

Other observations

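The 3 gene lists of this part, the genes named from them and the comparison of BMP4 with culture time were chosen after the first results were seen, and the test of the amino acid genes was fixed before its own result.

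Some of the genes that BMP4 raised by 12 h also rose in culture without it. Of the 80 genes higher with BMP4 at 12 h, 23 were called higher in untreated explants at 24 h than at 0 h, where 1.51 would be shared by chance, and 2 lower. The chance values here and below assume independent calls. These fits take all or part of their spread from the 12 h arrays, and a gene with a small spread there is called more readily in each. The chance values can therefore be too low. Both calls held for MYH7B, MYL2, MYH15 and ACTC1. Of the 40 genes lower with BMP4 at 12 h, 1 was called lower in untreated explants at 24 h, against 0.264 by chance, and 5 higher, against 0.757. Over both agents, where BMP4 arrays enter the difference of 24 h and 3 h, 42 of the 80 were also higher, against 4.50 by chance, and 10 of the 40 also lower, against 1.72. The arrays of that difference do not overlap with those of 12 h, though its spread comes in part from them. Across the 120 genes called at 12 h, which are not independent replicates, the BMP4 effect correlated with the untreated difference of 24 h and 3 h with r = 0.285, and 67.5% had the same sign, while over all 11675 genes r was 0.134 and the share 54.5%. FGF8, called lower with BMP4 at 12 h, had an untreated signal of 1635 at 3 h and 2209 at 24 h, and of 126 with BMP4 at 24 h.

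Some of the leading genes lie outside the lists of heart muscle and signaling. TH had untreated signals of 4.7 to 136 and BMP4 signals of 7.8 at 3 h, 557 and 596 at 12 h and 593 at 24 h. PRPS2 had a signal of 4309 with BMP4 at 24 h against 151 without, and ALPPL 2047 against 79.6. CDKN2B had signals of 68.4 at 0 h, 4101 at 3 h untreated and 3444 at 3 h with BMP4.

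A list of genes of placodes and of anterior neural ectoderm was written because several of them had been seen to fall, so its 19 measured members restate that: 4 fell across times and 9 at 24 h. Leaving out the named genes and the called members of other lists can pull the median toward 0. The 10 members left had a median of −0.70 at 24 h with a standard error across genes of 0.56. Of these, 7 were below 0 and SIX3 (−3.31, adjusted p = 0.0138) passed the test, while NEUROG1 (−2.47) and EYA1 (−1.81) did not. Others that fell at 24 h include PAX6, FOXI2 (−4.87 ± 0.65), EYA2, ISL2 (−3.03 ± 0.39) and SOX3. The list shares EYA2 with the anterior heart field list, SOX3 and PAX6 with that of neural tissue, and DLL1, HES5 and HES6 with that of Notch. Markers of surface ectoderm and general epithelium had a median of 0.10 across times, with none of 18 past the test. At 24 h KRT7, KRT14 (1.63 ± 0.26) and KRT24 rose, and the abundant EPCAM (0.10 ± 0.13), CDH1 (0.25 ± 0.25) and CLDN1 (−0.02 ± 0.13) did not pass the test.

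After 3 h of culture without BMP4, genes of amino acid synthesis and transport were among the highest, and a candidate explanation is a wider response to amino acid shortage or to explantation. Of 34 measured members of such a list 9 rose, with a median of 0.96, among them PSPH, CHAC1, CEBPB (3.84), STC2 (2.91), ASNS (2.66) and ALDH18A1 (2.39). The 27 members outside the leading and named genes were taken as not seen before the list was written. Their median was 0.66, with 24 above 0 and 2 past the test, and 0% of 10000 random lists of matched signal had a median as high. Genes of the random lists were drawn independently. The share therefore does not allow for genes of 1 pathway moving together in 1 array. From 3 h to 24 h over both agents the list's median was −0.77 and 19 members fell. The 0 h and 3 h samples are 1 array each, so a difference in handling between them stays open.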
